A study of Homo sapiens with 12 samples.

How the data were processed

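DU145 cells, an established human prostate cancer cell line, were sorted by the submitters into ALDH- and ALDH+ populations with the Aldefluor assay, and 1000 cells were injected into each NMRI nude mouse that had received 4 Gy to the whole body. Tumours longer than 7 mm received 0 or 50 Gy in 30 fractions of 0 or 1.67 Gy. RNA was isolated from the frozen tumours, and libraries were made from 500 ng RNA with the TruSeq Stranded mRNA kit. The groups, taken from the labels, were ALDH- control, ALDH- 50 Gy, ALDH+ control and ALDH+ 50 Gy, with 3 libraries each, 12 in all.

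The deposited values are raw counts per gene, 57820 genes for each library, in 3 columns: reads without regard to strand and reads on either strand. The submitters' processing notes list STAR 2.5.3a, SAMtools, featureCounts and Subread 1.5.1 with the human genome hs37d5 (GRCh37), without their roles or order. They do not say how reads of the mouse host, duplicates or reads mapping to several places were handled. Counts on the strand that the kit reports for a gene's own transcript were used, and unstranded counts were an alternative. The choice of strand was checked on the totals, of which antisense reads made up 5.46% to 6.44%. Sense counts ranged from 33867000 to 52540000 a library.

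Tests were done in R 4.3.3 with edgeR 4.0.16 (filterByExpr by group, TMM factors, robust quasi-likelihood F test), in 1 fit of all 12 libraries with a mean for each group. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and the 18562 genes passing the filter were tested. Contrasts were irradiation in ALDH- and in ALDH+ tumours, ALDH+ against ALDH- in control and in irradiated tumours, the difference between the irradiation changes, and the irradiation and population changes averaged over the other factor. The SE of a log2 fold change was its size over the square root of F. Group levels are TMM-normalised CPM (counts scaled to library size) with SD, and log2 CPM used a prior count of 2. The common biological coefficient of variation was 0.376.

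Lists of genes were tested with camera of limma 3.58.1 (preset correlation between genes of 0.01), with an estimated correlation and fry as alternatives, and adjusted over the lists within each contrast. They were the ALDH family, retinoid signalling, p53 targets, replication, mitosis, double-strand break repair, interferon response, senescence-associated secretion, mesenchymal, epithelial and stem cell genes, hypoxia, NRF2 targets, cholesterol synthesis, androgen receptor targets, squamous and neuroendocrine genes, and markers of fibroblasts, endothelium, macrophages, skeletal muscle, adipocytes and erythroid cells. For a list, genes past the threshold were counted both over all genes and adjusted over the list alone. Ribosomal protein genes (81, of which 79 were tested) were added as a class after the data were seen. Shares of counts were compared with a two-sided exact permutation test in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

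The groups, contrasts, lists and the first set of alternatives were chosen before the data were examined. Genes were named by a rule: among called protein-coding genes with a mean of at least 1 CPM in the higher group and replicate values that did not overlap, the 10 with the largest log2 fold change in each direction for the contrasts of 2 groups, and 5 for the others (overlap allowed in the averaged ones). Chance alone gives groups of 3 that do not overlap in 10% of genes. From each list up to 4 called members with the smallest p were eligible. Where fewer than 5 genes passed, the 5 smallest p were given as values that did not pass, and ALDH1A1 and ALDH1A3 were always given. Genes withheld for evaluation were left out of those named. Which of the named genes are described first, with coordinates, and which list members are given as examples was chosen after their values were seen. Gene type, GC content and transcript length came from GENCODE v29, which matched 96.9% of the tested genes.

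That first set was no filter, a filter of at least 1 CPM in at least 3 libraries, median-of-ratios and upper-quartile factors, a block for the replicate number, a test against a fold change of 1.5, DESeq2 1.42.0, limma voom with sample quality weights, only the libraries of a contrast, and each library left out in turn. Unstranded counts were added once the files were in hand. Alternatives chosen after seeing the data were scaling by library totals, removal of ribosomal protein genes, leaving out ALDH+ control libraries 1 and 2 together or ALDH+ 50 Gy libraries 1 and 3 together, and an offset for GC content and transcript length, alone and with the block. For the offset, each library's log2 deviation from the mean of all libraries was fitted by natural splines of GC content (5 degrees of freedom) and log2 transcript length (3). No label says that replicate numbers pair libraries, and 4 of 12 pairs with the same number had a correlation of residuals over 0.1 (range -0.51 to 0.387), so no block was used.

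The procedure was tested on simulated data with the observed depth and spread. Of 100 genes changed 4-fold, 63, 73, 67 and 68 were found in the 4 contrasts of 2 groups, and of 100 changed 2-fold 3, 3, 4 and 5, with 3, 3, 6 and 9 unchanged genes called. With an added GC trend, 1089 unchanged genes were called without the offset and 3 with it. That trend was linear in GC content, and no length trend was added. The list test found the 1 list that was moved and none of 20 others. Simulated genes varied independently of each other, so this does not check gene calls where many genes of a library shift together. In the observed libraries the first principal component held 63.7% of the variance. Nor does it check list calls where the genes of a list are correlated. For irradiation in ALDH- tumours the estimated correlation was 0.374 for interferon and 0.41 for hypoxia genes.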

Results

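Gene expression was measured by RNA sequencing in 12 libraries from xenografts of DU145, a human prostate cancer cell line, grown under the skin of immune-deficient nude mice. The tumours were started from cells sorted with the Aldefluor assay, which stains cells by their aldehyde dehydrogenase (ALDH) activity, into an ALDH- and an ALDH+ population. Tumours of each population received no dose (control) or 50 Gy in 30 fractions, which gave 4 groups of 3 libraries each. Counts on the gene's own strand ranged from 37279000 to 51079000 in the ALDH- control libraries, from 38937000 to 44725000 in the ALDH- 50 Gy, from 33867000 to 48188000 in the ALDH+ control and from 34418000 to 52540000 in the ALDH+ 50 Gy libraries. The labels do not say whether each library came from a separate animal, so the p-values measure only the spread between these samples.

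ALDH+ control libraries 1 and 2 held the largest shares of ribosomal protein mRNA, and all 3 ALDH+ control libraries the smallest shares of antisense reads. Ribosomal protein mRNAs took 21.5% ± 6.79 (SD, n = 3) of the counts in them, against 10.4% ± 4.74 in ALDH- control, 12.6% ± 0.964 in ALDH- 50 Gy and 8.21% ± 2.72 in ALDH+ 50 Gy libraries. ALDH+ control libraries 1 and 2 held 23.3% and 27.2%, and library 3 held 14.0%, less than the 14.8% of ALDH- control library 2. The 13 mitochondrially encoded mRNAs took 1.55% ± 0.168 in ALDH+ control, 3.74% ± 1.47 in ALDH+ 50 Gy, 2.90% ± 2.15 in ALDH- control and 1.56% ± 0.749 in ALDH- 50 Gy libraries. Antisense reads made up 5.46% to 5.51% of stranded counts in the ALDH+ control libraries and 5.86% to 6.44% in the other 9. In 16 two-sided exact permutation tests of these shares and of the share of the top 10 genes, the smallest p was 0.1 (adjusted p = 0.229), which is the smallest that 3 against 3 libraries allow. The first principal component held 63.7% of the variance, with ALDH+ control libraries 2 and 1 at 148 and 132 and ALDH- control 3, ALDH+ 50 Gy 3 and ALDH+ 50 Gy 1 at the other end, at -116, -106 and -98.5. Counts on human genes that mark cell types of the host differed by gene: COL1A1, a main collagen of fibroblasts, ranged from 0.472 to 32.9 CPM, COL3A1, another, reached at most 0.54 CPM, PTPRC, the pan-leukocyte marker, at most 0.081 CPM, and HBB, of red blood cells, had 0 counts in every library. The CPM of these markers were scaled to library totals alone, without TMM factors.

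**Figure D1:**
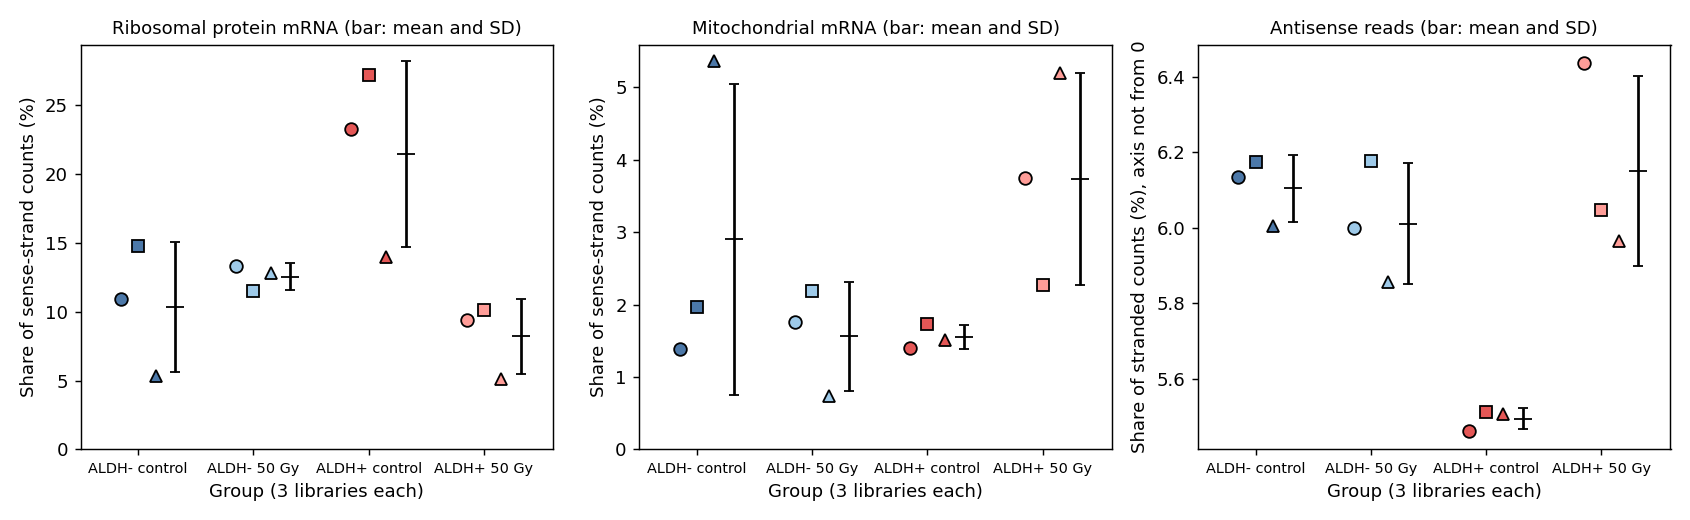
Share of counts per library (%, vertical axes; the antisense axis does not start at 0) in the 4 groups of 3 libraries, for ribosomal protein mRNAs, mitochondrially encoded mRNAs and antisense reads; circles, squares and triangles are replicates 1, 2 and 3, and bars are the mean and SD. ALDH+ control libraries 1 and 2 hold 23.3% and 27.2% ribosomal protein mRNA, and all 3 ALDH+ control libraries hold 5.46% to 5.51% antisense reads.

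ALDH1A1 (ENSG00000165092.8, chromosome 9, 75515578 to 75695358 on GRCh37), which encodes a retinaldehyde dehydrogenase that the Aldefluor assay detects, was lower in irradiated than in control ALDH+ tumours. Its level was 118 ± 88.3 CPM (SD, n = 3) in ALDH+ control and 16.7 ± 15.2 CPM in ALDH+ 50 Gy tumours, a log2 fold change of -2.82 (SE 0.76, adjusted p = 0.00833). In ALDH- tumours it was 81.1 ± 48.4 CPM without and 140 ± 33.5 CPM with irradiation, a log2 fold change of 0.78 (SE 0.71, adjusted p = 0.620). The difference between these 2 changes was -3.60 on the log2 scale (SE 1.03, adjusted p = 0.0125). The populations did not differ in ALDH1A1 past the threshold, either in control tumours (log2 fold change 0.54, SE 0.71, adjusted p = 0.541) or in irradiated tumours (-3.06, SE 0.76, adjusted p = 0.276). The ALDH+ control libraries held 204, 121 and 27.9 CPM and the ALDH+ 50 Gy libraries 34.0, 10.7 and 5.47 CPM, so that ALDH+ control library 3 lay below ALDH+ 50 Gy library 1. Without ALDH+ control libraries 1 and 2, the irradiation change in ALDH+ tumours was -0.74 (SE 0.85, adjusted p = 0.566), and with an offset for GC content and transcript length it was -1.51 (SE 0.68, adjusted p = 0.0932). ALDH1A3 (ENSG00000184254.12, chromosome 15, 101417919 to 101456831), another retinaldehyde dehydrogenase, passed the threshold in no comparison. Its log2 fold change under irradiation was -2.15 in ALDH- tumours (SE 0.71, adjusted p = 0.527; 24.9 ± 11.3 against 5.58 ± 2.20 CPM) and 0.11 in ALDH+ tumours (SE 0.68, adjusted p = 0.902).

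**Figure D2:**
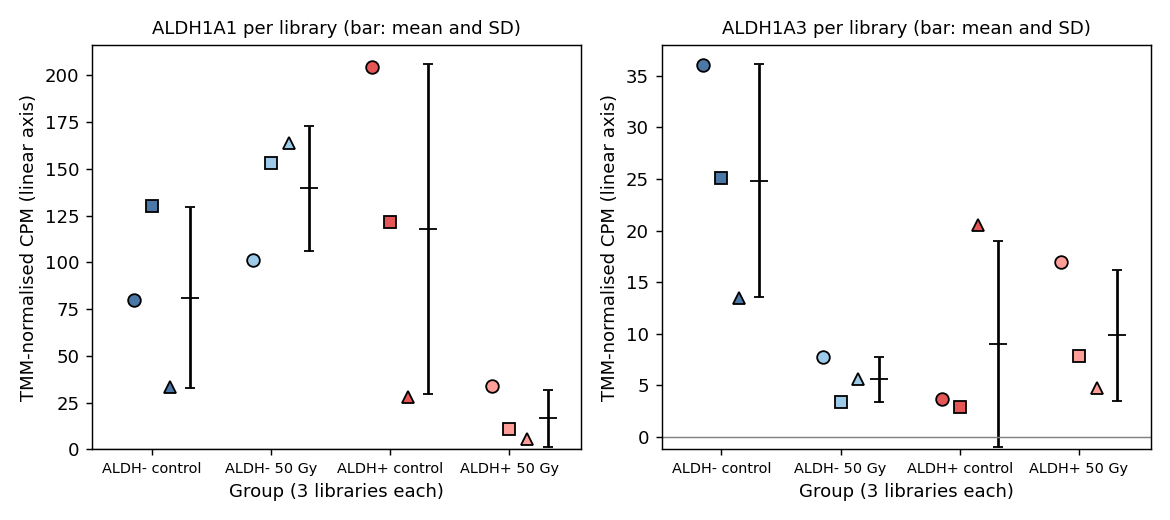
TMM-normalised CPM (vertical, linear) of ALDH1A1 and ALDH1A3 in each library of the 4 groups; circles, squares and triangles are replicates 1, 2 and 3, and bars are the mean and SD (n = 3). ALDH1A1 spans 27.9 to 204 CPM within the ALDH+ control group and 5.47 to 34.0 CPM in the ALDH+ 50 Gy group.

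The first comparison asked how tumours grown from ALDH+ cells responded to irradiation. Of 9 tested fibroblast markers (of 19 listed) 7 were higher after 50 Gy, of 12 mesenchymal genes 6 were higher, and of 79 ribosomal protein genes 68 were lower, while camera called no list. TNC (ENSG00000041982.10, chromosome 9, 117782806 to 117880536), the matrix glycoprotein tenascin C, rose from 1.41 ± 0.369 to 39.6 ± 33.7 CPM (SD, n = 3), a log2 fold change of 4.79 (SE 0.82, adjusted p = 0.00247). PLEC (ENSG00000178209.10, chromosome 8, 144989321 to 145050902), the cytoskeletal linker plectin, rose from 8.68 ± 2.99 to 293 ± 234 CPM (log2 fold change 5.07, SE 1.02, adjusted p = 0.00263). DEFB1 (ENSG00000164825.3, chromosome 8, 6728097 to 6735544), an antimicrobial beta-defensin, fell from 42.7 ± 41.5 to 0.45 ± 0.342 CPM (log2 fold change -6.61, SE 1.25, adjusted p = 0.00248). TFF3 (ENSG00000160180.14, chromosome 21, 43731777 to 43735761), a trefoil peptide of mucous epithelia, fell from 14.3 ± 12.2 to 0.252 ± 0.161 CPM (log2 fold change -5.87, SE 1.16, adjusted p = 0.00259). These values are without the offset for GC content and transcript length. Of the values of named genes over all contrasts, 164 kept their direction and side of the threshold with the offset. Another 64 no longer passed and 10 reversed.

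In all, 9745 of the 18562 tested genes passed the edgeR quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05, 5094 of them higher and 4651 lower after irradiation. Other genes with the largest rises that the rule named were CCND2 (cyclin D2, log2 fold change 5.26, from 0.0446 ± 0.00707 to 1.79 ± 1.74 CPM), DMBT1 (a secreted mucosal glycoprotein, 4.38), C6orf223 (4.14), SULT1C2 (a sulfotransferase, 4.07) and KCNH2 (a potassium channel, 4.04). NPIPB3 and NPIPB5 (4.82 and 4.34) belong to a family of near-identical copies, so reads may have been shared between them and their values are uncertain. The other genes with the largest falls were AGR3 (a protein disulfide isomerase, -5.55), CLEC19A (a C-type lectin, -5.23), RHOH (-4.86), HOPX (a homeodomain cofactor, -4.65), PLA2G12B (-4.53), FXYD3 (a regulator of ion transport, -4.16) and DDC (aromatic amino acid decarboxylase, -4.06). GSTA1 (a glutathione transferase, -4.83) has close paralogs and is uncertain for that reason. Of 79 tested ribosomal protein genes, 68 fell and none rose (median log2 fold change -2.07), with 45 to 71 falling under the other scalings tried and 1 rising with the GC and length offset. Fold changes are relative to a median over all genes of 0.13, which scaling by library totals alone moved to 0.85. With that scaling 7757 genes were higher and 1838 lower.

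Lists of genes fixed before the data were examined showed the following in this comparison. Over all 18562 tested genes 5094 rose and 4651 fell. The rising shares of interferon and epithelial genes were close to that of all genes. Of 19 listed fibroblast markers 9 had enough counts to be tested. Of these 9, 7 rose and none fell (median log2 fold change 2.57), among them the collagen genes COL5A2 (3.24), COL1A1 (3.11) and COL6A1 (2.57). With the GC and length offset 2 fibroblast markers rose (median 0.81). Of 12 mesenchymal genes, 6 rose and none fell, among them ITGA5, a fibronectin receptor subunit (2.43), FN1, fibronectin (2.27), and VIM, vimentin (1.39). Of 15 stem cell genes, 5 rose and 2 fell, with the receptor NOTCH1 at 3.44, the integrin ITGA2 at 2.73, the transcription factor KLF4 at 1.68 and the histone methyltransferase EZH2 at -0.77. Of 25 epithelial genes, 7 rose and none fell, among them PKP3 (2.73) and DSP (1.69), both of desmosomes. With the offset 4 epithelial genes rose and 2 fell. Of 35 interferon response genes, 9 rose and 1 fell, with OAS3 at 2.79, PARP14 at 1.87 and STAT2 at 1.52. Of 28 mitosis genes, 5 rose and 11 fell, with the spindle-associated HMMR at -2.50, the kinase CDK1 at -1.94 and the kinesin KIF2C at 1.15. With the offset 7 mitosis genes rose and 8 fell (median -0.078). Of 28 p53 targets, 11 rose and 4 fell, with the stress-induced SESN2 at 2.08 and PHLDA3 at 1.93. Of 27 replication genes, 9 rose and 9 fell, with UHRF1 at 2.76 and the polymerase subunit POLE2 at -2.30. Of 31 double-strand break repair genes, 8 rose and 9 fell, with RAD54L at 1.20 and the checkpoint kinase CHEK2 at -1.52.

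Among metabolic lists, 7 of 21 cholesterol synthesis genes rose and 9 fell, with the regulator SREBF2 at 2.35 and the enzyme MSMO1 at -2.47. Of 19 hypoxia genes, 4 rose and 5 fell, with the glycolytic PFKFB3 at 2.62 and PGK1 at -2.01. With the offset 1 hypoxia gene rose and 3 fell (median 0.068, against 0.57 without it). Of 21 NRF2 targets, 3 rose and 7 fell, with AKR1C3, which has close paralogs, at -2.87. Of 18 ALDH family genes, 4 rose and 2 fell, with ALDH1L2 at 1.99 and ALDH9A1 at -1.78. Of 15 retinoid genes, 6 rose and 4 fell, with the receptors RXRA at 2.53 and RARA at 2.51 and RARRES1 at -2.31. Of 20 senescence-associated secretion genes, 5 rose and 3 fell, with the cytokines LIF at 2.29 and IL8 at -2.69. Of 10 androgen receptor targets, 3 rose and 1 fell (SLC45A3, 2.91), of 11 squamous genes 3 fell and none rose (S100A9, -2.33), and of 5 neuroendocrine genes 1 rose (ENO2, 2.11) and 1 fell (DDC). Of the other cell type lists, 4 of 8 macrophage genes rose (CSF1R, the receptor of macrophage colony-stimulating factor, 3.18), 5 of 11 skeletal muscle genes rose and 1 fell, 1 of 4 adipocyte genes rose (PLIN4, 3.98), none of 6 endothelial genes passed, and none of the 6 erythroid genes had enough counts to be tested. The full lists held 19 macrophage, 21 skeletal muscle, 9 adipocyte and 15 endothelial genes, of which the rest had too few counts. Adjusted over the list alone, the counts were the same except for replication (10 higher, 10 lower), mitosis (6 higher) and epithelial genes (5 higher). The offset turned the median of 6 lists. For the ALDH family it went from 0.10 to -0.44 (1 higher, 3 lower), for cholesterol synthesis from 0.26 to -0.49 (4 higher, 9 lower), for replication from 0.058 to -0.21 (5 higher, 7 lower) and for endothelial genes from 0.63 to -0.29. For senescence-associated secretion it went from -0.25 to 0.50 (3 higher, 1 lower) and for double-strand break repair from -0.19 to 0.042 (8 higher, 6 lower).

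No list moved against the other genes by camera (smallest adjusted p = 0.0618, fibroblast). Interferon genes did with the offset (adjusted p = 0.0376), fibroblast genes with the replicate block (adjusted p = 0.0399), and fibroblast and interferon genes upward and mitosis genes downward without ALDH+ control libraries 1 and 2 (adjusted p = 0.0356 each). The test fry, which tests a list's own direction, found macrophage (adjusted p = 3.2e-04), fibroblast (0.0183), stem cell (0.0183), mesenchymal (0.0188) and endothelial genes (0.0344) higher. Summed over the macrophage list, CPM scaled to library totals were 24.7, 18.2 and 60.4 in ALDH+ control libraries 1, 2 and 3. They were 76.6, 55.9 and 47.9 in ALDH+ 50 Gy libraries 1, 2 and 3. Whether counts on these markers came from cells of the mouse host was not tested. Median, mean and camera direction differed in sign for the retinoid, replication, senescence, cholesterol and androgen receptor lists. Without ALDH+ control libraries 1 and 2 together, or without ALDH+ 50 Gy libraries 1 and 3 together, edgeR called 0 genes, with 4821 and 4521 at an unadjusted p under 0.05. The median log2 fold change of the 9745 genes, in the direction called, was then 1.15 in both cases, against 1.66 with all libraries. Without the 2 control libraries TNC stood at 4.62 and PLEC at 4.64, and the falls shrank to -2.81 for DEFB1 and -3.09 for TFF3, each with an adjusted p of 0.173 or 0.174.

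**Figure D3:**
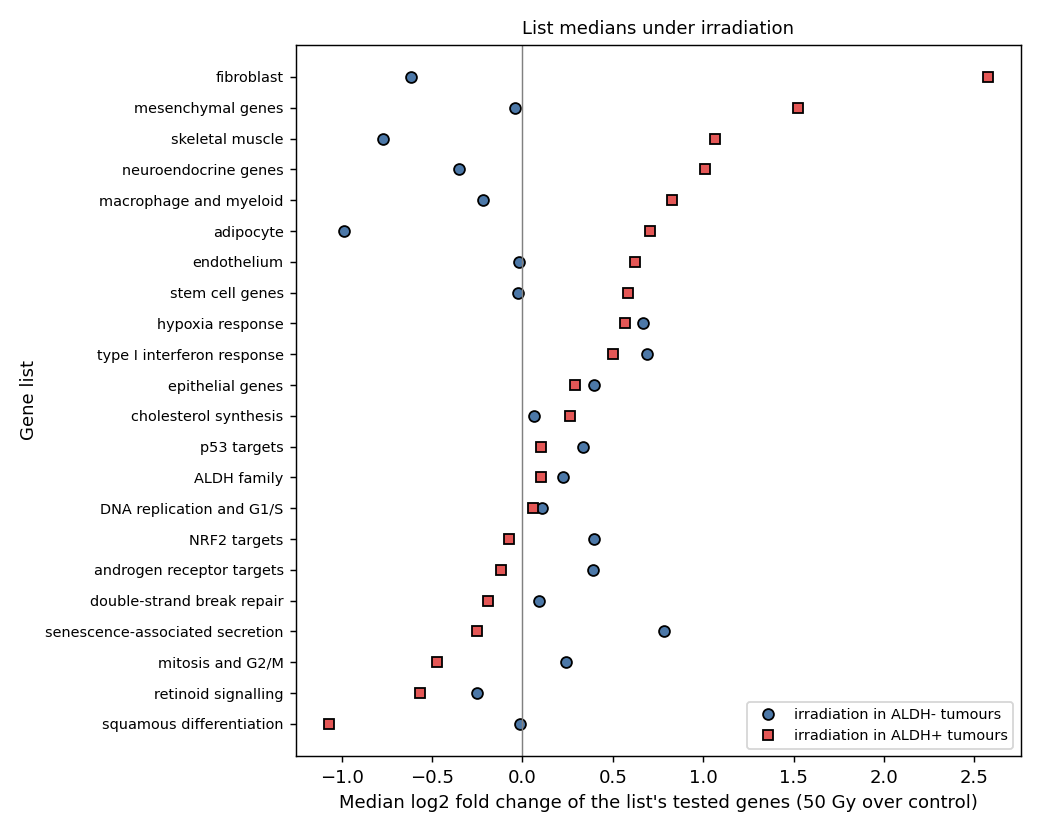
Median log2 fold change (horizontal, 50 Gy over control) of the tested genes of each list (vertical) in ALDH- tumours (circles) and ALDH+ tumours (squares), 3 libraries per group. The fibroblast list lies at 2.57 in ALDH+ and -0.62 in ALDH- tumours, and the interferon list at 0.50 and 0.69.

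The second comparison asked the same of tumours grown from ALDH- cells. No single gene passed, and camera called 7 lists higher with a preset correlation between genes and 0 with an estimated one (adjusted p from 0.472 to 0.558). The genes with the smallest p did not pass: VTCN1, an immune checkpoint ligand, had a log2 fold change of 3.17 (SE 0.59, adjusted p = 0.527), from 0.111 ± 0.0326 to 0.998 ± 0.473 CPM (SD, n = 3). MRC2 (ENSG00000011028.9, chromosome 17, 60704762 to 60770958), a collagen-binding endocytic receptor, had -3.82 (10.5 ± 9.16 against 0.741 ± 0.174 CPM), CARD6 had 1.70, the matrix metalloproteinase MMP7 had 3.29 and the calcium pump ATP2C2 had 2.07, each at the same adjusted p. By edgeR 0 genes were called, with 1691 at an unadjusted p under 0.05, while DESeq2 called 57, limma voom with sample weights 5117 and edgeR with no filter on low counts 916.

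In the camera test with a preset correlation between genes, 7 of 22 lists moved up. These were the interferon response (median log2 fold change 0.69, adjusted p = 1.72e-07), hypoxia (0.67, adjusted p = 1.19e-05), NRF2 targets (0.40, adjusted p = 4.62e-05), senescence-associated secretion (0.79, adjusted p = 2.11e-04), p53 targets (0.34, adjusted p = 2.38e-04), epithelial genes (0.40, adjusted p = 0.0156) and mitosis (0.24, adjusted p = 0.0453). None of these 7 held with an estimated correlation (adjusted p = 0.472 for the first 5 named, 0.558 for epithelial genes and mitosis) or by fry, and mitosis did not hold with the offset (adjusted p = 0.323). Over all genes no list member passed, and adjusted over the list alone 1 hypoxia gene was higher and 1 adipocyte gene lower. The other 15 tested lists did not move by camera, including the ALDH family (median 0.22, adjusted p = 0.362) and double-strand break repair (0.09, adjusted p = 0.928). With the offset the ALDH family was called higher (adjusted p = 0.0494). Median, mean and camera direction differed in sign for double-strand break repair, mesenchymal, squamous, endothelial and macrophage genes.

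The third comparison asked whether the irradiation changes differed between the populations. By edgeR with all 12 libraries, 9171 genes passed the test of the difference. Of these, 4961 had a more positive change in ALDH+ and 4210 a more negative one. With library totals alone these were 7306 and 1641, and the median over all genes was 1.05, against 0.15 with TMM. Groupings that exchanged only ALDH- libraries between control and 50 Gy, tried after the results were seen, called 0 to 8878 genes. A high count can thus arise without the real ALDH- groups. Without ALDH+ control libraries 1 and 2 the median difference of the 9171 genes, in the direction called, was 1.70, against 2.24. The largest positive differences were PLEC at 7.20 (SE 1.34), the lipid droplet protein PLIN4 at 7.06 (SE 1.41), the microtubule-associated MAP1A at 6.99 (SE 1.59), NPIPB3 at 6.93 (SE 1.51) and KCNH2 at 6.92 (SE 1.57). The largest negative differences were DEFB1 at -8.09 (SE 1.58), AGR3 at -7.78 (SE 1.81), TFF3 at -6.67 (SE 1.46), RHOH at -6.33 (SE 1.20) and PLA2G12B at -5.70 (SE 1.10), with adjusted p from 0.00435 to 0.00548 over these 10 genes. PLEC, for example, went from 108 ± 113 to 24.7 ± 12.5 CPM in ALDH- tumours (SD, n = 3), against 8.68 ± 2.99 to 293 ± 234 CPM in ALDH+ tumours.

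For the same contrast, 6 of 9 fibroblast genes had a more positive change in ALDH+ tumours and none a more negative one (median difference 3.07; with the offset 1 gene, median 1.16), and so did 4 of 12 mesenchymal genes (1.38) and 3 of 8 macrophage genes (1.01). Of 28 mitosis genes 11 had a more negative and 5 a more positive change (median -0.74; with the offset 9 and 6, median -0.13), of 21 NRF2 targets 8 and 3 (-0.46), and of 79 ribosomal protein genes 60 and 0 (-2.47), with 45 to 65 under the other scalings and 1 more positive with library totals or the offset. These counts of the 5 lists were the same adjusted over the list alone. The irradiation changes of retinoid, double-strand break repair and epithelial genes differed in sign between median, mean and camera direction. Camera called no list (smallest adjusted p = 0.0931, fibroblast), and fry called fibroblast (adjusted p = 0.0431) and macrophage genes (adjusted p = 0.00233). By camera, fibroblast genes were called more positive and mitosis and senescence-associated secretion genes more negative without ALDH+ control libraries 1 and 2 (adjusted p = 0.0414 each). The offset turned the median of interferon (-0.16 to 0.33), senescence-associated secretion (-0.54 to 0.63), double-strand break repair (-0.12 to 0.049) and endothelial genes (0.54 to -0.69). Across all 18562 genes, the log2 fold changes of the 2 irradiation comparisons, which share no library, ran in opposite directions (Pearson r = -0.608, Spearman rho = -0.679), and 21.7% of genes had the same sign. Without ALDH- control library 3 the Pearson r was -0.336. Genes are not independent replicates, so no p is given. By edgeR with the filter no gene was called in both, since that test called none in ALDH- tumours. Without ALDH+ control libraries 1 and 2 together, or without ALDH+ 50 Gy libraries 1 and 3 together, 0 genes passed by edgeR, with 6659 and 6186 at an unadjusted p under 0.05. The median difference of the 9171 genes, in the direction called, was then 1.70 and 1.74, against 2.24 with all libraries.

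The fourth comparison asked how unirradiated tumours of the sorted populations differed. Of 79 ribosomal protein genes 57 were higher in ALDH+ than in ALDH- control tumours, and 7 of 25 epithelial and 4 of 9 fibroblast genes were lower, while camera called no list. Over all 18562 tested genes 4023 were higher and 4616 lower, so the share of epithelial genes that were lower was close to that of all genes. GPX3 (ENSG00000211445.7, chromosome 5, 150400124 to 150408554), a secreted glutathione peroxidase, was 0.579 ± 0.369 CPM in ALDH- and 23.2 ± 35.5 CPM in ALDH+ tumours (SD, n = 3), a log2 fold change of 5.33 (SE 1.68, adjusted p = 0.0210). Without ALDH+ control library 3 the GPX3 change was 2.23 (adjusted p = 0.195). PLIN4 (ENSG00000167676.3, chromosome 19, 4502204 to 4517716) was lower, at 10.6 ± 14.2 against 0.405 ± 0.0461 CPM (log2 fold change -4.70, SE 1.07, adjusted p = 0.0057). NEFM (ENSG00000104722.9, chromosome 8, 24770525 to 24776607), a neurofilament protein, was lower at 2.01 ± 1.43 against 0.121 ± 0.092 CPM (log2 fold change -3.92, SE 0.79, adjusted p = 0.00504).

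Of the 18562 genes, 8639 passed, 4023 higher and 4616 lower in ALDH+ tumours. Other genes with the largest positive changes were CLLU1OS (3.80), C2orf15 (3.62), TFF3 (3.58), the protease inhibitor SPINK4 (3.53), the thyroid hormone deiodinase DIO1 (3.38), TNFRSF11B, the decoy receptor osteoprotegerin (3.33), and C3orf83 (3.07). KLRC2 (3.23) has near-identical relatives and RPS3A (3.08, from 1014 ± 801 to 8592 ± 5542 CPM) has many processed pseudogenes, so both values are uncertain. Other genes with the largest negative changes were the potassium channel KCNH6 (-4.50), NPIPB5 (-4.43, uncertain as above), ZFHX2 (-4.32), NAT8L, which makes N-acetylaspartate (-3.89), SSPO (-3.87), the semaphorin SEMA6A (-3.83), EVPL, the cell envelope protein envoplakin (-3.81), and C1orf95 (-3.81). Of 79 ribosomal protein genes 57 were higher and none lower (median 1.72), with 32 to 59 higher under the other scalings and 1 lower with library totals or the offset. The median over all genes was -0.11, and -0.78 with library totals, where 1316 genes were higher and 7166 lower.

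Of 25 epithelial genes 7 were lower and none higher (PKP3, -2.20; DSP, -1.83), of 9 fibroblast genes 4 were lower (COL1A1, -2.72), and of 12 mesenchymal genes 4 were lower (ITGA5, -1.85; TNC, -2.23). Of 15 retinoid genes 2 were higher and 4 lower (RXRA, -2.65; RARG, -2.25), and of 18 ALDH family genes 1 was higher (ALDH9A1, 1.33) and 4 lower (ALDH3B1, -1.95; ALDH4A1, -1.43). Of 28 p53 targets 7 were higher and 3 lower, with the death receptor FAS at 2.24 and the DNA repair factor XPC at -1.63. Of 28 mitosis genes 9 were higher and 6 lower (CDK1, 1.85; CENPF, -2.45), of 27 replication genes 7 and 9 (E2F1, -1.30), and of 31 double-strand break repair genes 10 and 6 (PARP1, -1.22). With the offset 6 mitosis genes were higher and 9 lower (median -0.019, against 0.44 without it), and 3 epithelial, 1 mesenchymal and no fibroblast genes were lower (fibroblast median -0.56, against -1.54). Of 21 cholesterol genes 9 were higher and 7 lower (SC5D, 2.29; DHCR7, -1.48), of 19 hypoxia genes 3 and 2 (PGK1, 1.86), of 21 NRF2 targets 3 and 5 (OSGIN1, -1.46), of 35 interferon genes 5 and 3 (CXCL10, 2.85; OAS3, -2.54), and of 20 senescence-associated secretion genes 4 and 2 (IL6, 1.74; LIF, -1.88). Stem cell genes had 1 higher and 4 lower of 15 (NOTCH1, -2.86), squamous genes 4 higher of 11 (KRT16, 1.83), neuroendocrine genes 1 higher and 3 lower of 5 (FOXA2, -2.02), androgen receptor targets 2 lower of 10 (FKBP5, -1.23), macrophage genes 3 lower of 8, muscle genes 1 higher and 3 lower of 11, adipocyte genes 2 lower of 4, and endothelial genes 1 lower of 6 (KDR, -2.09). Counts adjusted over the list alone (higher, lower) differed for p53 targets (6, 3), replication (9, 10), mitosis (10, 6), double-strand break repair (10, 7), interferon (4, 3), senescence-associated secretion (1, 2), stem cell (0, 4), hypoxia (2, 1), NRF2 (3, 4), cholesterol (9, 8), androgen receptor (0, 1), squamous (2, 0), fibroblast (1, 6) and adipocyte genes (0, 3).

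Camera called no list (smallest adjusted p = 0.394), and fry called 7 lower: macrophage (adjusted p = 0.00837), ALDH family (0.0221), neuroendocrine (0.0258), adipocyte (0.0258), retinoid (0.0367), endothelial (0.0367) and fibroblast genes (0.0497). With the offset the median of the ALDH family turned from -0.36 to 0.092 (2 genes higher, none lower) and that of endothelial genes from -0.28 to 0.60. It also turned those of replication (-0.039 to 0.13), interferon (0.023 to -0.22), NRF2 (-0.16 to 0.0049) and cholesterol genes (-0.52 to 0.13). Camera called senescence-associated secretion (adjusted p = 9.55e-04) and p53 targets (adjusted p = 0.0487) higher without ALDH+ control libraries 1 and 2. Median, mean and camera direction differed in sign for hypoxia genes and NRF2 targets. Without ALDH+ control libraries 1 and 2 edgeR called 0 genes, with 3631 at an unadjusted p under 0.05. The median log2 fold change of the 8639 genes, in the direction called, was then 1.04, against 1.56 with all libraries. The counts were 5044 without ALDH+ control library 2, 5127 without ALDH+ control library 1 and 5258 without ALDH- control library 3.

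The fifth comparison asked how irradiated tumours of the populations differed. No gene passed, and camera called 4 lists with a preset correlation between genes and 0 with an estimated one (adjusted p from 0.420 to 0.594). METTL7A (ENSG00000185432.10, chromosome 12, 51317255 to 51326300), a methyltransferase-like protein, had the smallest p and was 15.5 ± 0.673 CPM in ALDH- and 1.73 ± 0.192 CPM in ALDH+ tumours (SD, n = 3; log2 fold change -3.16, SE 0.52, adjusted p = 0.276). ASPHD1 (1.74), the potassium channel KCNQ5 (2.52), the ATP-gated channel P2RX5 (2.14) and the receptor kinase ROR1 (1.74) had the same adjusted p. By edgeR 0 genes were called, with 3341 at an unadjusted p under 0.05, while DESeq2 called 195, limma voom 3170 and edgeR with no filter on low counts 1658. Camera called NRF2 targets (median -0.55, adjusted p = 2.69e-05), mitosis (-0.46, adjusted p = 0.0102) and cholesterol synthesis (-0.48, adjusted p = 0.0121) lower, and fibroblast genes (1.53, adjusted p = 0.00156) higher. With an estimated correlation the adjusted p was 0.420 for NRF2 targets, 0.594 for mitosis and cholesterol and 0.590 for fibroblast genes, and with the offset it was 0.0553 for mitosis and for fibroblast genes. The offset also called the ALDH family (adjusted p = 3.16e-04), epithelial (0.00273), replication (0.0132) and hypoxia genes (0.0132) lower, so that 2 of its 6 lists were among the first 4. Fry called NRF2 targets and the ALDH family lower and macrophage genes higher (adjusted p = 0.0321 each). Adjusted over the list alone, 3 NRF2 targets and 2 ALDH family genes were lower and 5 fibroblast, 2 macrophage and 1 muscle genes were higher, and over all genes none was. Median, mean and camera direction differed in sign for retinoid, double-strand break repair, interferon, senescence and neuroendocrine genes.

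Averaged over both populations, edgeR called 2 genes higher after irradiation and none lower. DESeq2 called 1622 genes, limma voom 8035 and edgeR with no filter on low counts 2387. ST3GAL1 (ENSG00000008513.10, chromosome 8, 134467091 to 134584183), a sialyltransferase, rose by 2.04 on the log2 scale (SE 0.27, adjusted p = 0.0415), from 5.93 ± 1.46 to 8.35 ± 1.33 CPM in ALDH- and from 1.46 ± 0.577 to 17.6 ± 7.00 CPM in ALDH+ tumours (SD, n = 3). G0S2 (ENSG00000123689.5, chromosome 1, 209848765 to 209849733), an inhibitor of triglyceride breakdown, rose by 1.87 (SE 0.25, adjusted p = 0.0415), from 9.74 ± 2.79 to 18.1 ± 2.31 and from 8.04 ± 3.11 to 57.6 ± 23.4 CPM. TBC1D2 (1.53, adjusted p = 0.0503), B3GNT3 (adjusted p = 0.0591) and the secreted hormone STC2 (2.35, adjusted p = 0.0679) came next and did not pass. Camera called interferon response (median 0.54, adjusted p = 4.65e-06), epithelial (0.41, adjusted p = 0.00102), mesenchymal (0.78, adjusted p = 0.00441), hypoxia (0.49, adjusted p = 0.00891), fibroblast (0.82, adjusted p = 0.00891) and p53 target genes (0.24, adjusted p = 0.0113) higher. With an estimated correlation the adjusted p was 0.485 for these lists and 0.670 for hypoxia, and with the offset it was 0.107 for fibroblast genes. The offset also called senescence-associated secretion genes higher (adjusted p = 0.0034). Adjusted over the list alone, 8 interferon genes, 6 p53 targets, 4 mesenchymal, 4 hypoxia, 3 epithelial, 3 retinoid, 3 senescence-associated secretion, 3 NRF2, 2 stem cell, 2 androgen receptor, 1 fibroblast, 1 macrophage and 1 neuroendocrine genes were higher. The lower ones were 3 retinoid and 1 neuroendocrine genes. Median, mean and camera direction differed in sign for retinoid, cholesterol and neuroendocrine genes. By edgeR the count was 0 without either pair of ALDH+ libraries named above (1069 at an unadjusted p under 0.05 without the 50 Gy pair). It was also 0 without ALDH- control library 1 or 3, ALDH- 50 Gy library 2 or 3, ALDH+ control library 2 or ALDH+ 50 Gy library 1 or 3. The count was 1 without ALDH- control library 2, 5 without ALDH- 50 Gy library 1, 8 without ALDH+ 50 Gy library 2 and 2795 without ALDH+ control library 3.

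Averaged over both treatments, no gene differed between the populations past the threshold. The genes with the smallest p were the cytokine IL15 (1.29, SE 0.22), the cell adhesion molecule CEACAM5 (-1.62, SE 0.29), ACSM3 (-1.03, SE 0.20), the fatty acid desaturase SCD (-1.24, SE 0.25) and the chemokine CXCL16 (-1.26, SE 0.25), each with an adjusted p of 0.301. SCD was 639 ± 24.2 and 472 ± 162 CPM in ALDH- control and 50 Gy tumours and 139 ± 58.1 and 389 ± 94.2 CPM in the ALDH+ ones (SD, n = 3). By edgeR 0 genes were called, with 2868 at an unadjusted p under 0.05, while DESeq2 called 132, limma voom 5357 and edgeR with no filter on low counts 566. Camera called epithelial genes (median -0.45, adjusted p = 4.38e-05), NRF2 targets (-0.42, adjusted p = 0.00208) and the ALDH family (-0.31, adjusted p = 0.00962) lower in ALDH+ tumours, and fry called the ALDH family (adjusted p = 0.00898). With an estimated correlation the adjusted p was 0.568 for epithelial genes and NRF2 targets and 0.184 for the ALDH family, and with the offset it was 0.152 for the ALDH family. The offset also called p53 targets higher (adjusted p = 0.00323). No list member passed over all genes. With p adjusted over the list alone, 4 epithelial, 2 ALDH family, 1 retinoid, 1 replication, 1 androgen receptor and 1 neuroendocrine genes were lower. The higher ones were 2 p53 targets and 1 interferon gene. Median, mean and camera direction differed in sign for squamous, fibroblast, macrophage and muscle genes.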

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

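All tests of explanations and all splits below were chosen after the results were seen. The irradiation change differed between ALDH+ and ALDH- tumours for 9171 genes by the test of the difference itself. On the log2 scale the difference was 7.20 for PLEC, 7.06 for PLIN4, 6.99 for MAP1A, 6.93 for NPIPB3 and 6.92 for KCNH2, and -8.09 for DEFB1, -7.78 for AGR3, -6.67 for TFF3, -6.33 for RHOH, -5.70 for PLA2G12B and -3.60 for ALDH1A1. Of 100 splits of the libraries, 1, the real one, gave as many genes as 9171. The splits exchange treatment in both populations, so this share does not test whether 2 equal effects could give the count. The highest other split, 8878, kept every ALDH+ library in its own group and exchanged only ALDH- libraries.

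The first pattern weighed was the 9745 genes called for irradiation in ALDH+ tumours. The offset argues against the trend in GC content and transcript length that it models as the whole cause. After it 5286 genes were still called in the same direction. A trend of another form was not tested. Whether counts taken by ribosomal protein genes were the cause cannot be told. Without those genes 9664 were called, 9629 of them shared with the reported calls. Leaving them out moved no other result either, so that setting could not test this cause. What gave the ribosomal protein shares themselves was not tested. An origin in ALDH+ control libraries 1 and 2 stays open: with library 3 alone standing for the group, edgeR called 0 genes (4821 at an unadjusted p under 0.05), against 6113 with library 1 alone and 7065 with library 2 alone, the lone library being assumed to vary like the other groups. With library 3 alone the median log2 fold change of the called genes, in the direction called, was 1.15, against 1.66 with all libraries, which does not show these 2 libraries as the whole origin, nor, as the 50 Gy libraries are shared, exclude it. A response to irradiation particular to tumours of ALDH+ cells, the biological explanation that the design names, also stays open.

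The second pattern was the opposite sign of the irradiation fold changes in the 2 populations (r = -0.608, and -0.336 without ALDH- control library 3). The GC and length trend that the offset models is argued against as the whole cause by r = -0.517 after the offset. An axis along which libraries of the same group also differ stays open: the deviation of ALDH- control library 2 from its group correlated with the ALDH+ irradiation fold changes at r = -0.713, that of ALDH- control library 3 at 0.648, of ALDH- 50 Gy libraries 2 and 3 at 0.563 and -0.428, of ALDH- 50 Gy library 1 at -0.139 and of ALDH- control library 1 at -0.0144. Differences between tumours, in tissue handling or in RNA quality could each give such an axis, and no label separates these. Opposite responses of the populations stay open as well.

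The third pattern was the lower ALDH1A1 level in irradiated than control ALDH+ tumours (log2 fold change -2.82, SE 0.76). Over the alternatives tried its adjusted p ran from 1.29e-12 to 0.566, and every alternative kept its sign. With the offset it was -1.51 (SE 0.68, adjusted p = 0.0932), smaller and no longer called. With offset and block it was -1.58 (adjusted p = 0.0382). How much of the change the GC and length trend accounts for cannot be told. The fits with and without the offset use the same libraries, and their SE does not measure the difference between them. Without ALDH+ control libraries 1 and 2 it was -0.74 (SE 0.85, adjusted p = 0.566), so that these libraries may account for much of it. An effect of irradiation in ALDH+ tumours stays open.

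For irradiation in ALDH+ tumours 1 of 10 splits gave as many genes as the real 9745 (highest other 0), and for ALDH+ against ALDH- control tumours 1 of 10 (8639, highest other 0). For irradiation in ALDH- tumours and for the populations after irradiation the real count was 0 by edgeR (1691 and 3341 at an unadjusted p under 0.05; DESeq2 57 and 195, limma voom 5117 and 3170), the highest other was 0, and so all 10 of 10 splits gave as many. These 10 splits are too few for a share under 0.05. For irradiation averaged over the populations 6 of 100 splits gave at least the real 2 genes, with 10433 in the highest other, and for the populations averaged over treatment 100 of 100 gave at least the real 0 (2868 at an unadjusted p under 0.05; DESeq2 132, limma voom 5357), with 9171 in the highest other. Chance is not excluded for the 2 genes, and the second share says nothing, since every split gives at least 0. The split with 9171 is the contrast of the difference itself, and the one with 10433 kept every ALDH+ library in its own group.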

How the results depend on the processing

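Unstranded counts were added once the files were in hand, and the offset, library totals, removal of ribosomal protein genes and both pairs of left-out libraries were chosen after seeing the data; the cause of each change below was not tested unless stated. Of the values of named genes under all alternatives, 4566 kept their direction and side of the threshold, 90 came to pass it, 660 no longer passed and 33 reversed; of those of the 20 called lists 56 were kept and 44 no longer passed, and lists that came to pass are not in this tally. The counts for irradiation in ALDH+ tumours, ALDH+ against ALDH- control tumours and the difference were 9787, 8676 and 9074 with the replicate block, and 7371, 5927 and 6769 with the offset, of which 5286, 4178 and 4777 were shared with the reported calls.

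Counts of genes for irradiation in ALDH- tumours were 916 with no filter, 57 with DESeq2, 5117 with voom and 0 to 1 leaving out 1 library (1 without ALDH- control 2). For irradiation in ALDH+ tumours they were 0 without both ALDH+ control libraries 1 and 2, 0 without both ALDH+ 50 Gy libraries 1 and 3 (edgeR; 4821 and 4521 at an unadjusted p under 0.05) and 6897 to 10443 leaving out 1. For the control populations they were 13738 with voom, 5399 against a fold change of 1.5, 0 without both controls (3631 at an unadjusted p under 0.05) and 5044 (without ALDH+ control 2) to 9597 leaving out 1, with 5127 without ALDH+ control 1 and 5258 without ALDH- control 3. For the irradiated populations they were 1658 with no filter, 195 with DESeq2, 3170 with voom, 1 with only the libraries of the contrast and 0 leaving out any 1. For the difference they were 0 without either pair (6659 and 6186 at an unadjusted p under 0.05) and 7060 to 10353 leaving out 1. With 1 library left, it is assumed to vary like the other groups, and fewer libraries remove power.

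For irradiation averaged over populations counts were 2387 with no filter, 1622 with DESeq2, 8035 with voom, 4 with the block, 8 with library totals, 0 with the stricter filter, the fold test, the offset, the offset with block and without either pair, and 0 to 2795 (without ALDH+ control 3) leaving out 1. For the populations averaged over treatments they were 566 with no filter, 132 with DESeq2, 5357 with voom and 0 leaving out any 1. Lists called for irradiation in ALDH- tumours (7) were 0 with an estimated correlation and 0 by fry. In ALDH+ tumours (0) they were 5 by fry, 1 with the block, 3 without both controls and 1 with the offset. For control populations (0) they were 7 by fry and 2 without both controls, for irradiated populations (4) 0 with an estimated correlation, 3 by fry (1 of the 4), 6 with the block and 6 with the offset (2 of the 4), and for the difference (0) 2 by fry and 3 without both controls. For averaged irradiation (6) they were 0 with an estimated correlation and 1 by fry, and for averaged populations (3) 0, 1 and, without both controls, 6. The correlation of the irradiation fold changes was -0.747 at a mean CPM of at least 5, -0.517 with the offset, -0.488 with offset and block, -0.423 without both ALDH+ 50 Gy libraries and -0.668 to -0.336 (without ALDH- control 3) leaving out 1.

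With the offset, and with offset and block, log2 fold changes reversed for irradiation in ALDH+ tumours of ALDH16A1 (-0.13, -0.14), VEGFA (-0.18, -0.28), ABCC3 (-0.15, -0.15) and ALDH1A3 (-0.41, -0.42), and between control populations of ALDH16A1 (0.19, 0.20), CDT1 (0.036, 0.052), FANCA (0.32, 0.31), VEGFA (0.29, 0.45), ABCC3 (0.25, 0.25) and ALDH1A1 (-0.49, -0.69), and with block of CNFN (-0.029) and RYR1 (0.061). Without both controls ALDH1A3 reversed for irradiation in ALDH+ tumours (-1.06) and between averaged populations (0.28), ALDH1A1 between control populations (-1.53) and in averaged irradiation (0.023), and CNFN between control populations (-0.21). ALDH1A3 also reversed without both ALDH+ 50 Gy libraries (-0.19) and without ALDH+ control 1 (-0.26), ALDH+ control 2 (-0.30) or ALDH+ 50 Gy 1 (-0.54), and leaving out 1 library reached at most 1.57 (without ALDH+ control 3). ALDH1A1 reversed between control populations with library totals (-0.24) and without ALDH+ control 1 (-0.13), and leaving out 1 library reached at most 1.06 (without ALDH- control 2). Depth was not varied in the simulated data, in which few 2-fold changes were found with 3 libraries a group.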

Other observations

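All values here were computed after the results were seen. Gene length and GC content moved with the groups. Medians of the extremes of 13811 protein-coding genes, without ribosomal protein genes, were compared relative to the mean of all libraries. Transcripts of at most 1619 nt exceeded those of at least 7525 nt by 1.20 ± 0.62 on the log2 scale (SD, n = 3) in ALDH+ control libraries. The difference was -0.85 ± 0.75 in ALDH+ 50 Gy, -0.63 ± 0.97 in ALDH- control and 0.23 ± 0.38 in ALDH- 50 Gy libraries. Genes of at most 38.5% GC exceeded those of at least 61.8% by 1.25 ± 0.23 in ALDH+ control libraries, against -0.63 ± 0.71, -0.59 ± 0.40 and -0.04 ± 0.42 in the same order. GC content and length accounted for 43.3% ± 5.91 of the variance of a library's deviations in ALDH+ control, 32.2% ± 21.9 in ALDH+ 50 Gy, 30.9% ± 16.9 in ALDH- control and 17.5% ± 7.92 in ALDH- 50 Gy libraries.

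The 13 mitochondrially encoded mRNAs had 0 calls by edgeR for irradiation in ALDH+ tumours with TMM factors (median log2 fold change 0.56), and 11 were higher with the GC and length offset (median 1.84). With CPM scaled to library totals alone, COL1A1, a collagen gene, ranged from 0.472 to 32.9 CPM over the libraries, while COL3A1 stayed at or under 0.54 CPM and DCN, a proteoglycan gene of fibroblasts, at or under 0.054 CPM.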
